A study of Mus musculus with 6 samples.

How the data were processed

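Whole adrenal glands of female DBA/2J mice aged 4 months were profiled on a single-colour Illumina bead array, with 3 samples from gonadectomized mice (GDX) and 3 from non-gonadectomized controls (nGDX), which the labels call biological replicates. Per the labels' protocols, total RNA was amplified by linear in vitro transcription and labelled with biotin. The time between surgery and sampling is not given in the sources used here.

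The main values were the deposited mean bead intensity of each of 45281 probes on each array, a linear intensity per the file headers. The values show no background subtraction or normalization. A detection p-value per probe and array was deposited beside it, per the file headers, and the number of beads and the standard error over beads of each intensity were deposited as well. The scanner software and its version are not given in the sources used here. A second table holds the authors' processed intensity of the same probes. Its columns share 1 distribution, from -44.74 to 63881.43, with medians between 8.11 and 8.21, and 34.4% to 34.6% of the values in a column lie below 0. Those values are therefore background-subtracted, quantile-normalized intensities on a linear scale as far as the numbers show, and the method behind them is not given in the sources used here. Set against the unprocessed arrays, each nGDX column of the processed table matched the array of its own label with a rank correlation of 1. The GDX columns matched under other replicate numbers: the unprocessed GDX replicate 1 matched the processed replicate 2, replicate 2 matched replicate 3, and replicate 3 matched replicate 1. Group membership was the same in both tables, so only a fit that uses the replicate number as a block depends on this. Deviations of same-numbered arrays from their group means had correlations of -0.13, 0.010 and -0.32 with the numbers of the unprocessed table. With those of the processed table they were 0.33, 0.047 and 0.31, and 0.33 and 0.31 were the highest of all pairs between groups. A rule that asks for a correlation over 0.1 in every pair was met under neither numbering, but 1 weak pair is enough to fail it. A pairing under the numbers of the processed table is thus not excluded. The planned comparison held no covariate, so the replicate number was not a term of it. Replicate numbers in the text are those of the unprocessed table.

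Intensities were background-corrected and normalized with the neqc function of limma 3.58.1 in R 4.3.3, which here inferred the negative control distribution from the detection p-values, added an offset of 16, quantile-normalized the arrays and took log2. A probe was kept if its detection p-value was under 0.05 on at least 3 of the 6 arrays, which left 15827 probes. For each gene symbol, the kept probe with the highest mean over all 6 arrays was used, which gave 11918 genes. A symbol had more than 1 kept probe in 2972 cases. Of the 148 genes past the threshold, 34 had several kept probes, and in 0 of them a kept probe pointed the other way. Symbols are those of the array's annotation. Of 31508 probes with an Entrez identifier, 29586 matched a gene in the RefSeq table of assembly GRCm38.p6, which was used for current names and for which genes neighbour each other. The build of the coordinates in the array annotation is not stated, so only chromosome names are given. Probes of near-identical genes, such as Mup1 and Mup2, Gstm1 and Gstm2, Ugt1a6a and Ugt1a6b, or Tpsab1 and Mcpt6, may bind each other's transcripts.

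GDX was compared with nGDX by limma's linear model with empirical Bayes moderation (two-sided, 9.24 total degrees of freedom), with Benjamini-Hochberg adjustment over the 11918 genes and a threshold of 0.05 on the adjusted p. Errors of log2 fold changes are the standard errors (SE) of that fit, and n is 3 arrays per group throughout. Where a probe was above background on no array of a group, the fold is given as a bound. It is the mean log2 value of the brighter group minus the mean, in the dimmer group, of the higher of the probe's own value and the lowest value among detected probes on each array, turned into a fold. List medians are given as fitted, and with such genes at their bound where that moved the median. The bead arrays have no sequencing depth, and their number limits the precision.

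Before the data were examined, 32 gene lists were fixed, of which 30 had at least 3 measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Beside it stand camera with an estimated correlation and fry, both directional and mixed, where mixed fry asks for changes in either direction. The number of members past the threshold over all genes and adjusted over the list alone is given too. Also fixed then was the rule for named genes. It takes the 14 largest positive and 14 largest negative log2 fold changes among genes past the threshold whose 3 GDX arrays all lie on the same side of the 3 nGDX arrays, leaving out unnamed gene models. If fewer than 5 passed in a direction, the 5 with the smallest p would have been named as not past the threshold. It adds up to 4 members with the smallest p of each list described, the genes the study is known to have followed up, genes reported earlier in gonadectomy-induced adrenocortical neoplasia, and Star, Cyp11a1, Cyp11b1, Cyp11b2 and Cyp21a1. Genes named outside that rule are said to be so. A gene that the rule names is not reported here.

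The alternatives tried were other background corrections, other normalizations, other filters on dim probes, the authors' processed values (log2 of the value, floored at 0, plus 16), other probe rules, other variance models, array weights, the replicate number as a block (with the numbers of the processed table as well, an alternative chosen after seeing the data), and leaving out each array in turn. The test was tested on simulated data drawn from the means of the 11918 genes and their spreads in shuffled order, with 200 planted changes. At a planted log2 change of 1 it recovered 66% of the changed genes and at a change of 2 it recovered 97%, with 11 false calls among 174 and 0 calls of the wrong sign. The simulated noise was independent between genes, without array effects, background correction or filter, so these rates may not carry over to the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.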

Results

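Expression in whole adrenal glands was measured in 6 female DBA/2J mice aged 4 months, 3 of them gonadectomized (GDX) and 3 not (nGDX). DBA/2J is an inbred mouse strain. The title of the series names markers of gonadectomy-induced adrenocortical neoplasia as its subject, a lesion in which cells with gonadal features appear in the adrenal cortex. The labels call the arrays of a group biological replicates, and the number of arrays limits the precision. Between 15025 and 15702 of the 45281 probes were detected on 5 arrays, and 17820 on GDX replicate 3. Median intensities before normalization lay between 121 and 142, with a median of 40 to 43 beads per probe. The 95th percentile of intensity was 2413 on GDX replicate 3 and between 1030 and 1403 on the other 5 arrays. The labels also number that sample apart from the other 5, and whether it was processed separately is not given in the sources used here. After normalization, correlations between arrays of 1 group had a median of 0.983 (range 0.975 to 0.989), and those between groups a median of 0.977 (0.958 to 0.980). On the first principal component, which held 46.0% of the variance, nGDX replicate 1 lay at -1.38, nearer to the GDX arrays (13.2 to 28.3) than nGDX replicates 2 and 3 did (-20.4 and -36.0).

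The single comparison asked which genes differed between the adrenal glands of gonadectomized and control mice. The labels name the controls only as non-gonadectomized, so effects of the surgery and of the loss of the gonads cannot be told apart. After gonadectomy, the glands carried higher levels of several genes that gonadal steroidogenic and supporting cells use. Cyp17a1, which encodes the 17-alpha-hydroxylase needed for androgen synthesis and lies on chromosome 19, rose from the background level in all 3 nGDX arrays to a mean of 11.72 ± 0.28 (log2 intensity, SD, n = 3), at least 80.3-fold. That bound was 68.3-fold without GDX replicate 3, and without background correction the log2 fold change of Cyp17a1 was 4.49. Lhcgr, the luteinizing hormone receptor, was above background on 1 of 3 nGDX arrays and rose by 4.26 ± 0.27 on the log2 scale (SE), or 15.4-fold with undetected values raised to the lowest detected value of their array, and Inha, the inhibin alpha subunit, by 4.03 ± 0.39 (16.4-fold). The enzymes that make corticosteroids did not pass the test. The mast cell proteases Mcpt6 and Cma1 also rose, while Mup2, Apoc1 and C3 fell.

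In all, 96 of the 11918 genes were higher in GDX and 52 were lower at an adjusted p under 0.05 in limma's fit, 81 and 43 of them by at least 2-fold. At an unadjusted p under 0.05 the numbers were 762 and 770. In each of the 148 genes the 3 GDX arrays lay on 1 side of the 3 nGDX arrays. Such a separation was seen in 18.1% of all genes, and chance gives 10%. Among the higher genes, 20 were above background on no nGDX array and 17 on 1 or 2 of them, and among the lower genes 3 were above background on no GDX array and 9 on 1 or 2 of them, so the size of those changes depends on the background.

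**Figure D1:**
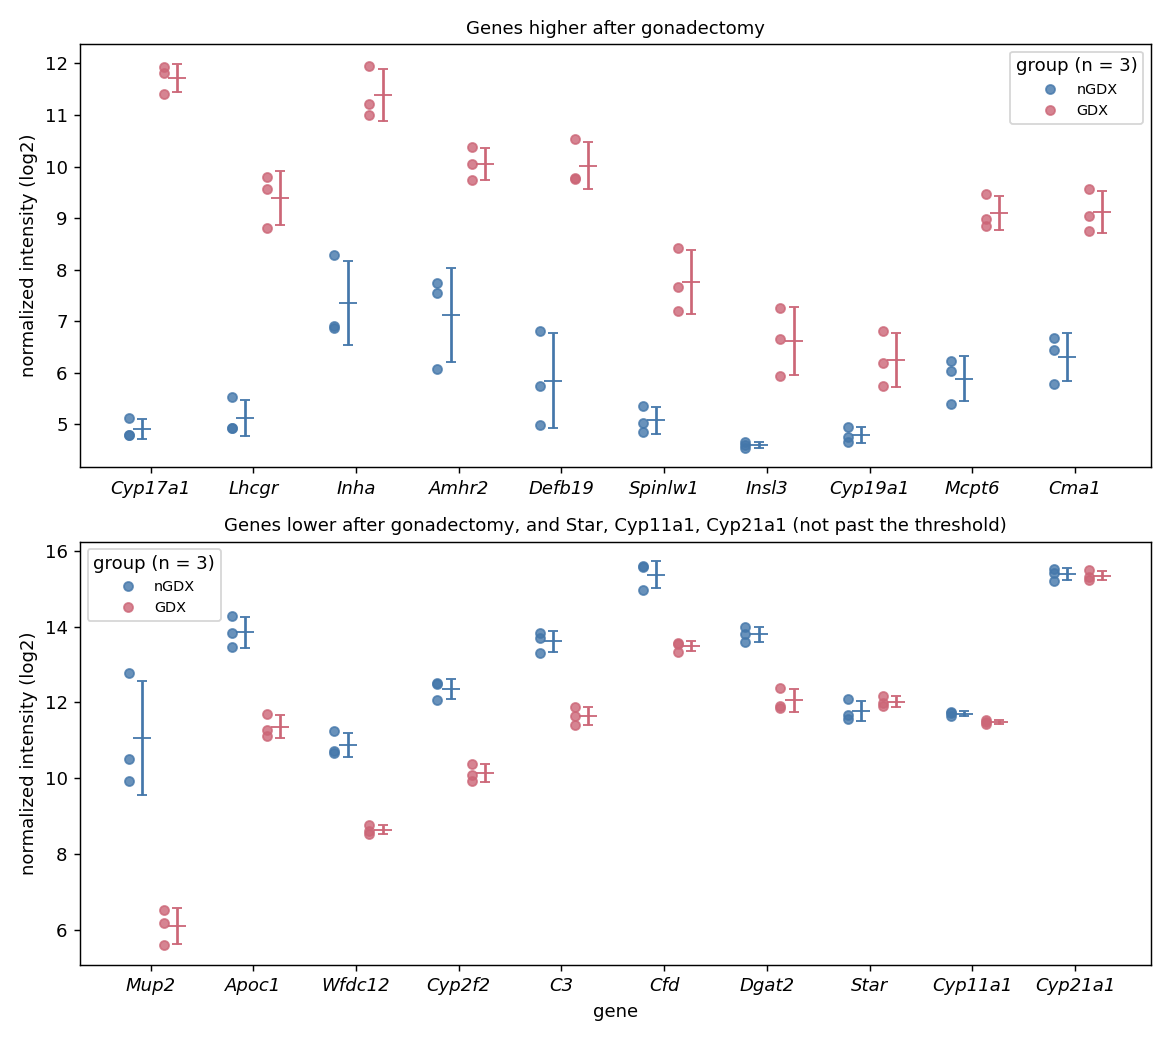
Normalized log2 intensity of 20 genes in each array (points, 3 nGDX in blue and 3 GDX in red), with the group mean and SD beside them. Cyp17a1 has a mean of 4.91 in nGDX and 11.72 in GDX, while Cyp21a1 differs by -0.038 on the log2 scale in the probe drawn (-0.38 in its other kept probe).

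Genes reported earlier in gonadectomy-induced adrenocortical neoplasia moved together. Of the 6 measured members, 5 rose and 1 did not pass, with a median log2 fold change of 3.48 (camera adjusted p = 6.0e-13; adjusted p = 0.104 with an estimated correlation), and 5 rose when adjusted over the list alone. Cyp17a1 had an adjusted p of 3.5e-07, Lhcgr of 1.2e-04 and Inha of 0.00113. Amhr2, the receptor of anti-Müllerian hormone, rose by 2.93 ± 0.39 (adjusted p = 0.00813). Cyp19a1, the aromatase that makes estrogens, was above background on no nGDX array and rose at least 1.82-fold (log2 fold change 1.45 ± 0.25, adjusted p = 0.0286). Its call was lost in 4 of the 6 fits that left out 1 array, without nGDX replicate 2, nGDX replicate 3, GDX replicate 2 or GDX replicate 3, with an adjusted p of up to 0.121. Inhba had a log2 fold change of 0.14 ± 0.22 (adjusted p = 0.832). Gata4 and Esr1 had no kept probe, and Inhbb and Wt1 had no probe under those symbols.

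Among the genes the study is known to have followed up, Spinlw1, now named Eppin and known as an epididymal protease inhibitor, was above background on no nGDX array and rose at least 5.18-fold (2.69 ± 0.29, adjusted p = 0.00206). Insl3, a peptide hormone of Leydig and theca cells, rose at least 2.34-fold from background (2.01 ± 0.29, adjusted p = 0.0116), and its call was lost without nGDX replicate 2 or nGDX replicate 3 (adjusted p of up to 0.0565). Foxl2, a transcription factor of granulosa cells, had a log2 fold change of 0.27 ± 0.15 (adjusted p = 0.510) and Igfbp6 one of -0.34 ± 0.17 (adjusted p = 0.458). Foxs1 had no probe under that symbol. In this list 2 of 4 measured members rose, also when adjusted over the list alone, with a median of 1.14, or 0.75 with Spinlw1 and Insl3 at their bound (camera adjusted p = 0.00542; adjusted p = 0.198 with an estimated correlation). The camera call was lost without background correction (median 0.42, adjusted p = 0.0662). The study chose these genes partly on the same arrays, so their direction is not independent evidence.

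Of 5 measured Sertoli cell markers 3 rose, with a median of 1.53 (camera adjusted p = 4.8e-08; adjusted p = 0.115 with an estimated correlation), and 4 rose when adjusted over the list alone. They were Defb19, a defensin (4.17 ± 0.41, adjusted p = 0.00124), Spinlw1 and Aard (1.53 ± 0.23, adjusted p = 0.0134), whose call was lost without nGDX replicate 3 (adjusted p = 0.0693). Sox9 had a log2 fold change of 0.67 ± 0.21 (adjusted p = 0.212). The Sertoli list held 14 members, and its unmeasured ones are named here outside the rule. Amh, Dmrt1, Rhox5, Cst9 and Ptgds were detected on no array, and no probe of Fshr or Gata1 on more than 1. Clu and Wt1 had no probe under those symbols. Of 7 Leydig cell markers 3 rose, with a median of 1.14 (camera adjusted p = 4.1e-07; adjusted p = 0.123 with an estimated correlation), and 5 rose when adjusted over the list alone. These were Cyp17a1, Lhcgr and Insl3, and Hsd17b3, which makes testosterone, had a log2 fold change of 1.14 ± 0.30 (adjusted p = 0.129). Of 11 granulosa and theca cell markers 3 rose, namely Inha, Amhr2 and Cyp19a1, with a median of 0.27 and a mean of 0.80 (camera adjusted p = 0.00446; adjusted p = 0.198 with an estimated correlation). Adjusted over the list alone, 4 rose and 1 fell. Fst, which encodes follistatin, had a log2 fold change of -0.84 ± 0.23 (adjusted p = 0.142). The gonadal lists share genes, so they are not separate pieces of evidence. A gene at background in nGDX, such as Spinlw1 or Insl3, enters a list only through its detection on the GDX arrays. The filter thus favours members that rose, and the medians and camera results hold for measured members only. Hsd3b6 of the Leydig list and Kitl and Esr2 of the granulosa list, named outside the rule, had no probe detected on more than 1 array. Of 7 transcription factors of the early gonad and adrenal primordium, 0 passed in limma's fit, 0 passed when adjusted over the list alone and 2 were higher at an unadjusted p under 0.05. Their median was -0.12 (0.11 with median scaling), their mean 0.09 and the direction of the test upward (camera adjusted p = 0.912).

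Enzymes of sex steroids and of corticosteroids were 2 separate lists. Of 13 enzymes of androgen and estrogen metabolism 3 rose, Cyp17a1, Cyp19a1 and Srd5a2, with a median of 0.17 and a mean of 0.74 (camera adjusted p = 0.00856; adjusted p = 0.238 with an estimated correlation). Adjusted over the list alone, 5 rose and 1 fell. Srd5a2, a steroid 5-alpha-reductase, rose by 0.98 ± 0.18 (adjusted p = 0.0343), and its call was lost in 4 of the 6 fits that left out 1 array, without nGDX replicate 2, nGDX replicate 3, GDX replicate 1 or GDX replicate 2 (adjusted p of up to 0.153). The camera call of the list was lost without GDX replicate 3 (adjusted p = 0.0672) and without background correction (adjusted p = 0.0569). The median log2 fold change of list sex_steroid_enzymes turned to -0.015 without the filter on dim probes, and it was 0.072 without nGDX replicate 2, 0.29 without GDX replicate 1 and 0.11 without GDX replicate 2 or GDX replicate 3. Without nGDX replicate 2, nGDX replicate 3 or GDX replicate 2, 1 member passed. Of 18 genes of corticosteroid synthesis and its ACTH response, 0 passed in limma's fit, 0 passed when adjusted over the list alone, and 2 were higher and 2 lower at an unadjusted p under 0.05 (median 0.037, camera adjusted p = 0.588). This list did pass in mixed fry, which counts changes in either direction (adjusted p = 0.00311). Star, which moves cholesterol into mitochondria, had a log2 fold change of 0.25 ± 0.18 (adjusted p = 0.628) and Cyp11a1, the side-chain cleavage enzyme, one of -0.22 ± 0.14 (adjusted p = 0.559). Cyp21a1 had -0.038 ± 0.16 (adjusted p = 0.943), Cyp11b1, the last enzyme of corticosterone synthesis, -0.37 ± 0.15 (adjusted p = 0.346) and Cyp11b2, the aldosterone synthase, 0.95 ± 0.41 (adjusted p = 0.382). The value of Cyp21a1 is that of its brighter probe (mean level 15.36). Its other kept probe (mean level 11.86) differed by -0.38.

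Other genes with large increases were Slc38a5, an amino acid transporter (at least 5.82-fold, adjusted p = 1.0e-04), Mia1 (3.12 ± 0.29, adjusted p = 9.3e-04), Kctd14 (3.06 ± 0.17, adjusted p = 8.0e-05), Susd3 (2.79 ± 0.22, adjusted p = 4.4e-04) and Cited1, a transcriptional coactivator (2.78 ± 0.21, adjusted p = 3.7e-04). Cacng5 rose by 2.69 ± 0.32 (adjusted p = 0.00387). Each of these calls was kept in all 6 fits that left out 1 array, but that of Cacng5 was lost without the filter on dim probes (adjusted p = 0.0764). The bound of Slc38a5 was 4.67-fold without GDX replicate 3. Its log2 fold change was 1.31 without background correction and 1.82 with normexp background.

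Of 7 measured mast cell markers 5 rose, with a median of 1.76 (camera adjusted p = 8.8e-11; adjusted p = 0.104 with an estimated correlation), and 6 rose when adjusted over the list alone. Without background correction the median was 0.66, and with normexp background and an offset of 50 it was 0.95. Mcpt6, a tryptase now named Tpsb2, rose by 3.21 ± 0.25 (adjusted p = 4.1e-04), the chymase Cma1 by 2.82 ± 0.27 (adjusted p = 0.00113) and the carboxypeptidase Cpa3 by 2.31 ± 0.27 (adjusted p = 0.00353). Fcer1a, a chain of the IgE receptor, rose at least 1.83-fold from background (1.59 ± 0.23, adjusted p = 0.0129), and its call was lost without nGDX replicate 3, GDX replicate 2 or GDX replicate 3 (adjusted p of up to 0.0588). Medulla markers were shifted as a list by a median of 0.29 (camera adjusted p = 0.00446; adjusted p = 0.245 with an estimated correlation), with 0 of 15 members past the threshold in limma's fit, 0 when adjusted over the list alone and 1 higher at an unadjusted p under 0.05. Npy was at 0.37 ± 0.15 (adjusted p = 0.329).

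**Figure D2:**
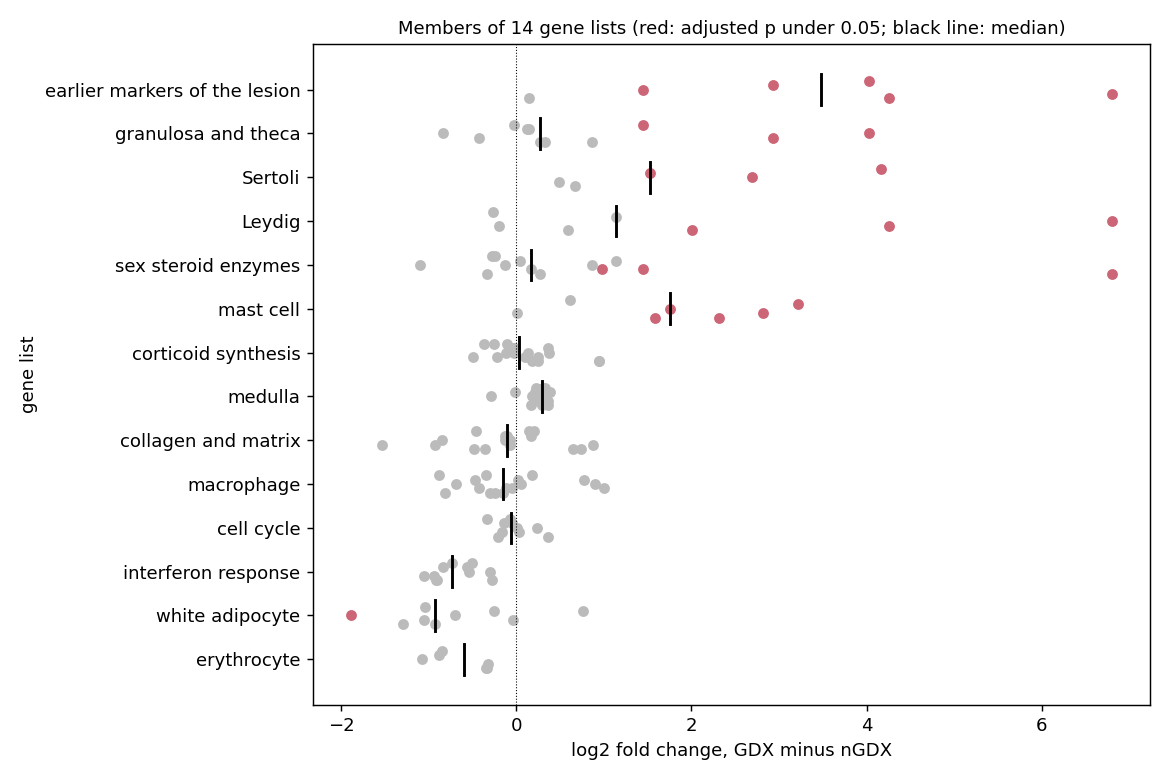
Log2 fold change (GDX minus nGDX) of each measured member of 14 gene lists, with members at an adjusted p under 0.05 in red, the others in grey and the list median as a black line. The earlier markers have a median of 3.48 and the mast cell list one of 1.76, while corticoid synthesis lies at 0.037.

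Among the genes named by the rule, the largest decreases in the main fit were in Mup2 and Mup1, members of the major urinary protein family. For Mup1 this depends on the background: its log2 fold change was -1.73 without background correction and -2.23 with normexp background. Apoc1 was at -2.26 or lower under every alternative run. Mup2 fell by 4.97 ± 0.62 (adjusted p = 0.00509), and its 3 nGDX arrays lay at 10.49, 9.93 and 12.77. With a trended and robust variance the log2 fold change of Mup2 had an adjusted p of 0.0903 and the log2 fold change of Mup1 one of 0.105, so both calls were lost. Mup1 was above background on no GDX array and was at least 9.48-fold higher in nGDX (adjusted p = 0.0209), a call lost without any 1 of the GDX replicates 1, 2 and 3 (adjusted p of up to 0.0731). That bound was 5.87-fold without nGDX replicate 3 and 15.5-fold without nGDX replicate 2. Without nGDX replicate 3 the log2 fold change of Mup2 was -4.13, or 17.5-fold against 31.3-fold. Cyp4f18 fell by 2.54 ± 0.36 (adjusted p = 0.0115), and its call was lost without nGDX replicate 3 (adjusted p = 0.0565). Apoc1, an apolipoprotein, fell by 2.49 ± 0.24 (adjusted p = 0.00113), Wfdc12 fell by 2.24 ± 0.19 and the cytochrome P450 gene Cyp2f2 fell by 2.22 ± 0.19 (adjusted p = 6.1e-04 for both). Apof fell by 2.10 ± 0.26 (adjusted p = 0.00530) and Elfn1 fell by 1.99 ± 0.20 (adjusted p = 0.00125). C3, the central complement component, fell by 1.97 ± 0.20 (adjusted p = 0.00125), and Hamp, the iron hormone hepcidin, fell by 1.90 ± 0.25 (adjusted p = 0.00793). Dgat2, an enzyme of triglyceride synthesis, fell by 1.74 ± 0.20 (adjusted p = 0.00282). Cxadr fell by 2.01 ± 0.30 (adjusted p = 0.0129), a call lost without nGDX replicate 2 or GDX replicate 2 (adjusted p of up to 0.0532). Acaa1b fell by 1.81 ± 0.30 (adjusted p = 0.0244), a call kept only without nGDX replicate 1 (adjusted p of up to 0.121 without each of the others).

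White adipocyte markers were lower as a list, with a median of -0.92 (camera adjusted p = 7.7e-04; adjusted p = 0.432 with an estimated correlation). Of 9 measured members 1 fell, Cfd, which encodes the complement protease adipsin (log2 fold change -1.88 ± 0.20, adjusted p = 0.00176). Adjusted over the list alone, 6 fell and 1 rose. The shift rests on nGDX replicates 2 and 3: the mean deviation of the list was 0.67 and 0.59 there, -0.19 on nGDX replicate 1, and -0.49, -0.15 and -0.42 on the GDX arrays. Without nGDX replicate 1 the median log2 fold change of list white_adipocyte was -1.36 and 5 members passed. On all 6 arrays the list did not pass in directional fry (adjusted p = 0.185) but did in mixed fry (adjusted p = 0.0116). Cidec had a log2 fold change of -1.04 ± 0.31 (adjusted p = 0.173) and Lpl, named outside the rule, one of -1.30 ± 0.47 (adjusted p = 0.279). Lep, the leptin gene, was the 1 member of the 9 above 0, at 0.76 ± 0.24 (adjusted p = 0.213). Interferon response genes had a median of -0.73 (camera adjusted p = 4.9e-08; adjusted p = 0.198 with an estimated correlation), with 0 of 11 past the threshold in limma's fit, 8 lower at an unadjusted p under 0.05 and 8 lower when adjusted over the list alone. Without nGDX replicate 1 the median log2 fold change of list interferon_response was -0.48. Irf7 was at -1.05 ± 0.21 (adjusted p = 0.0506) and Usp18 at -0.94 ± 0.21 (adjusted p = 0.0745). Red blood cell genes had a median of -0.60 (camera adjusted p = 0.0463; adjusted p = 0.734 with an estimated correlation), with 0 of 6 past the threshold in limma's fit, 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone. That camera call was lost without background correction (adjusted p = 0.0634) and in 4 of the 6 fits that left out 1 array, those without nGDX replicate 2, nGDX replicate 3, GDX replicate 1 or GDX replicate 3 (adjusted p of up to 0.511). The median log2 fold change of list erythrocyte was -0.94 without nGDX replicate 1 and -0.205 without nGDX replicate 3.

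Genes of glutathione and xenobiotic metabolism went both ways. Of 15 measured members 4 rose and 1 fell, and 5 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.217, mixed fry adjusted p = 5.1e-05). Aldh1a1, which makes retinoic acid, rose by 1.97 ± 0.19 (adjusted p = 0.00113). Hmox1, the inducible heme oxygenase, rose by 1.30 ± 0.20 (adjusted p = 0.0180), a call lost without nGDX replicate 2, nGDX replicate 3 or GDX replicate 2 (adjusted p of up to 0.0952). Gstm1 rose by 1.27 ± 0.21 (adjusted p = 0.0219), a call lost without nGDX replicate 2, nGDX replicate 3, GDX replicate 1 or GDX replicate 2 (adjusted p of up to 0.103). Cyp2f2 was the member that fell. Of 10 measured cell cycle genes 0 passed in limma's fit, 0 passed at an unadjusted p under 0.05 and 0 passed when adjusted over the list alone (median -0.059, or 0.18 with median scaling, camera adjusted p = 0.912). The list held 20 members. Those without a kept probe include Mki67, Ccnb1, Aurkb, Plk1 and Pcna, named outside the rule, so the result holds for the measured members only.

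Markers of further cell types in the gland were not past camera's list test. In mixed fry the matrix (adjusted p = 0.0186), macrophage (0.00912) and capsule and stroma lists (0.0127) passed. The endothelial (0.869) and zona glomerulosa lists (0.696) did not pass there. Of 12 endothelial genes 0 passed in limma's fit, also at an unadjusted p under 0.05 and when adjusted over the list alone (median 0.038, camera adjusted p = 0.614). Of 17 collagen and fibroblast matrix genes 0 passed, while 3 were higher and 2 lower when adjusted over the list alone and 3 and 3 at an unadjusted p under 0.05 (median -0.11, or 0.061 with median scaling, camera adjusted p = 0.601). Of 17 macrophage genes 0 passed, while 2 were higher and 3 lower when adjusted over the list alone and 3 and 3 at an unadjusted p under 0.05 (median -0.15, or 0.017 with median scaling, camera adjusted p = 0.241). Of 11 zona glomerulosa markers 0 passed, 0 when adjusted over the list alone and 1 was higher at an unadjusted p under 0.05 (camera adjusted p = 0.755). Of 10 capsule and stroma markers 1 fell, Mfap5, a microfibril protein (-1.07 ± 0.19, adjusted p = 0.0354), and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.622). The call of Mfap5 was lost without nGDX replicate 2, nGDX replicate 3, GDX replicate 2 or GDX replicate 3 (adjusted p of up to 0.145). With median scaling the log2 fold change of Mfap5 had an adjusted p of 0.953, without the filter on dim probes one of 0.118 and with the replicate number as a block one of 0.128. Of 17 cholesterol synthesis genes 0 passed, 0 when adjusted over the list alone, and 6 were higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.145, or 0.0484 with median scaling). The list of inhibin, activin and TGF-beta signalling had 2 of 14 members that rose, Inha and Amhr2, and 3 that rose and 1 that fell when adjusted over the list alone (camera adjusted p = 0.119, or 0.00282 with median scaling). It passed in directional fry (adjusted p = 0.0128).

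Of the gene lists, 11 passed in camera with the preset correlation, 0 with an estimated correlation (7 at an unadjusted p under 0.05) and 10 with directional fry. Mixed fry, which counts changes in either direction, passed 18. Without background correction the list medians were smaller, at 2.18 for the earlier markers, 0.56 for Sertoli, 0.53 for Leydig and 0.12 for granulosa and theca markers, 0.083 for sex steroid enzymes and -0.34 for red blood cell genes. With normexp background and an offset of 50 they were 0.80 for Sertoli, 0.58 for Leydig and 0.13 for granulosa and theca markers, 0.65 for the genes followed up and -0.40 for red blood cell genes. Median scaling gave 0.39 for sex steroid enzymes and 0.48 for the medulla. Of the 39 called genes among those named by rule, 19 lost the call without the filter on dim probes (among them Aard, Acaa1b, Amhr2, Apof, Cacng5, Cpa3, Cxadr, Cyp19a1, Cyp4f18, Fcer1a, Gstm1, Hamp, Hmox1, Insl3, Mfap5, Mup1, Mup2 and Srd5a2), 7 with median scaling (among them Acaa1b, Cyp19a1, Gstm1, Hmox1, Mfap5 and Srd5a2), 5 without background correction (Aard, Acaa1b, Cyp19a1, Fcer1a and Mup1) and 5 with the replicate number as a block (among them Cyp19a1, Gstm1, Mfap5 and Srd5a2). Without background correction 26 of the 39 log2 fold changes moved by over 1.5 times, among them those of Cyp17a1 (4.49), Lhcgr (2.29), Defb19 (2.58), Spinlw1 (1.13), Mcpt6 (1.81) and Mup1 (-1.73), and 13 did with normexp background. Of further genes given as a bound, Insl3 was at 0.76, Cyp19a1 at 0.49 and Fcer1a at 0.57 without background correction. With the replicate number as a block, genes higher in GDX numbered 46 and genes lower in GDX 25, against 130 and 95 with the numbers of the processed table, a fit chosen after seeing the data. Leaving out 1 array moved the count of genes higher in GDX from 96 to 144 without nGDX replicate 1, 49 without nGDX replicate 2, 48 without nGDX replicate 3, 60 without GDX replicate 1, 49 without GDX replicate 2 and 62 without GDX replicate 3, and the count of genes lower in GDX from 52 to 133, 22, 23, 24, 23 and 49 in that order.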

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

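The block with the replicate numbers of the processed table was chosen after seeing the data. Of the 39 called genes among the named and fixed ones, 20 stayed past the threshold under each of the alternatives run, among them Cyp17a1 (4.49 to 7.22), Lhcgr (2.29 to 4.60) and Inha (3.20 to 4.51), and 26 in all 6 fits that left out 1 array. Over 739 fits of these genes, 79 lost the call and 0 reversed. Without a filter on dim probes, genes higher in GDX numbered 36 and genes lower in GDX 13, with more genes tested, and 19 called genes lost the call, among them Amhr2, Mup2 and Cpa3. Median scaling gave 57 higher and 21 lower and moved the median log2 fold change of all genes from -0.0021 to 0.19; array weights gave 269 and 233; normexp background with an offset of 50 gave 92 lower, and the trend and robust fit 95 lower. The cause was not tested. Leaving out 1 array gave 48 to 144 higher and 22 to 133 lower genes, and 10 to 13 gene lists.

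With the replicate number as a block, genes higher in GDX numbered 46, genes lower in GDX 25 and gene lists 11; the numbers in the processed table gave 130, 95 and 11. Which numbering is right is not given in the sources used here. With an estimated correlation 0 lists passed, against 11 with the preset, 10 with directional fry and 18 with mixed fry. Some values reversed. The log2 fold change of Cyp21a1 (-0.038) was at 0.0074 with median scaling and between -0.12 and 0.027 in the fits without 1 array, above 0 without nGDX replicate 1 or GDX replicate 2 (0.016). The log2 fold change of Inhba lay between -0.041 (without nGDX replicate 2) and 0.40. The median log2 fold change of list sex_steroid_enzymes was -0.015 without the filter. The cause was not tested. In the array correlation, the median within groups exceeded that between groups by 0.00576, by 0.00650 on the authors' processed values and by 0.00266 without the filter. The slide as a block was not run, since no slide is given in the sources used here. Signal over background limits genes such as Insl3 and Cyp19a1, which were at background in nGDX.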

Other observations

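Tests chosen only after the result they measure was seen were those on Y-linked probes, on a dim array, on the share of cortical cells, on connective tissue and on adipocyte genes left out of the covariate. Markers of the X zone, a transient inner layer of the mouse adrenal cortex, were too few for a list test. Akr1c18 had a log2 fold change of -1.10 ± 0.32 (limma adjusted p = 0.167) and Pik3c2g one of -1.51 ± 0.36 (adjusted p = 0.0937), and both passed when adjusted over the list alone. GDX replicate 3 differed from the other GDX arrays: Akr1c18 was at 13.65 there against 12.49 and 12.34, and at 13.67 to 14.13 in nGDX. Pik3c2g was at 11.00 against 9.56 and 9.64, and at 11.26 to 11.85 in nGDX. Further interferon-induced genes, chosen after their values were seen, were past the threshold: Gbp3 (-1.26 ± 0.22, adjusted p = 0.0325), Cd274 (-0.94 ± 0.17, adjusted p = 0.0339) and the probe of LOC100038882, whose Entrez identifier now belongs to Isg15 (-1.29 ± 0.22, adjusted p = 0.0259).

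On GDX replicate 1 the 4 probes of Xist, the RNA of the inactive X chromosome, were at background (detection p 0.394 to 0.789, mean log2 intensity 4.74), while on the other 5 arrays each probe was detected (means 7.40 to 8.20). Xist was chosen after its values were seen. On that array 0 of 10 probes of Ddx3y, Eif2s3y, Kdm5d and Uty were detected. This argues against a male animal only if those probes work, as none was detected on the other arrays either. A dim array is argued against by 99.9% of 2782 genes near Xist's unnormalized level being detected there (99.7% to 100% on the other arrays for their own such genes). The median difference of those genes in unnormalized log2 intensity was -0.36, however. A single X chromosome in that animal would lower genes that escape X inactivation: the 4 measured (Utx -0.79, Eif2s3x -0.62, Ddx3x -0.17 and 2610029G23Rik -0.12) had a median deviation of -0.39 (log2), as low as in 1.23% of 10000 random lists of X-linked genes, but short of the -0.4 set beforehand. With 4 genes it stays open as a candidate explanation, as do degraded RNA and loss of Xist expression, which were not tested.

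The rise of mast cell genes may reflect more mast cells in or on the glands after gonadectomy, which the arrays cannot count. A lower share of the cortical cells would raise other cell types alike, but the highest median among the medulla, endothelium, matrix and macrophage lists was 0.293 against 1.76 for mast cells. It was 0.48 against 1.90 with median scaling and 0.22 against 0.66 without background correction, where the lists came closest: the lower quartile of the mast cell genes was 0.42 and the highest upper quartile of the 4 lists 0.30. Connective tissue attached to the GDX glands stays open: the matrix list had a median of -0.11 (0.061 with median scaling), but 6 of its members were higher and 11 lower, and its median level in nGDX of 9.24, against 6.30 for mast cell genes, would hide a small share. Mast cells in fat or capsule around the gland stay open too, as does an effect of gonadectomy itself, untested.

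The fall of 52 genes could come from less fat attached to the GDX glands, since the white adipocyte list was lower too, apart from nGDX replicate 1, which lay among the GDX arrays. Lep went the other way in that list (0.76). The brown adipocyte list did not pass (median -0.25, camera adjusted p = 0.456) and did not separate the groups. Its mean deviations were -0.69, 0.52 and 0.47 on nGDX replicates 1, 2 and 3, and -0.66, 0.48 and -0.11 on GDX replicates 1, 2 and 3. With the mean of the 8 uncalled adipocyte genes as a covariate, the median log2 fold change of the 52 genes went from -1.30 (interquartile range -1.92 to -1.07) to -1.16 (-1.75 to -0.92), 89.4% of its size, and 85.7% with all 9 adipocyte genes. Of the 52 genes 10 were still past the threshold (4 with all 9), and all 52 kept their sign with the covariate of 8. The covariate costs a degree of freedom and goes with the group (correlation -0.67). How much of the loss of calls this accounts for was not tested. Cfd, 1 of the 52 and left out of the covariate of 8, went from -1.88 to -1.60. The 7 uncalled adipocyte genes below 0, each fitted with the mean of the other uncalled ones, kept 17.9% of their median (-0.92 to -0.17). This contrast cannot decide the question, as the covariate's slope comes from the spread within groups. The 52 genes were picked for a difference large against that spread, so they tend to keep their size. The 7 were picked as uncalled, so they tend to shrink. Less fat on the GDX glands stays open. Liver RNA in the nGDX samples would bring Mup genes. Alb, detected on 0 of 3 nGDX arrays, argues against it only if its single probe works, as it was detected on no GDX array either. The median of -0.23 over the liver probes detected on all nGDX arrays comes from Serpina1 genes, whose high level would hide a small share. Ttr was detected on 1 nGDX array and no GDX array (-1.43), and Apoa1 on 1 nGDX and 3 GDX arrays (-0.35). Liver RNA thus stays open. An effect of gonadectomy itself, which the design names, stays open and untested for these genes.

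Some genes past the threshold are next to each other in the order of the tested genes in GRCm38.p6: 5 pairs among the 77 higher genes placed in it, and 3 pairs among the lower ones. Of the 5 pairs, 3 form a single cluster of Wfdc6a, Spinlw1, Wfdc6b and Wfdc10 on chromosome 2, and the others are Gstm1 with Gstm2 and Ugt1a6a with Ugt1a6b. The lower pairs are Gbp6, now named Gbp7, with Gbp3, Mup2 with Mup1, and Apoc4 with Apoc1. Wfdc6a, Wfdc6b, Wfdc10, Gstm2, Ugt1a6a, Ugt1a6b, Gbp6, Gbp3 and Apoc4 were chosen after their values were seen. The pairs were counted after some of them had been noticed, so the counts test no explanation. Gstm1 with Gstm2, Ugt1a6a with Ugt1a6b and Mup2 with Mup1 are near-identical genes whose probes were not tested for shared transcripts.

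The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 96 higher and 52 lower genes, and the highest count in either direction among the other splits was 0, so that 1 of the 10 splits gave as many. Each other split has GDX and nGDX arrays on both sides, so the difference between the groups adds to the spread within a side. Low counts there were thus likely beforehand, and no conclusion about chance is drawn from them.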
